A study of Mus musculus with 4 samples.

How the data were processed

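Total RNA of 4 C2C12 cultures was measured on Affymetrix arrays, 2 from cells with an empty plasmid and 2 from a polyclonal line with Myolinc in the same plasmid, per the labels. The deposited expression values are log2 values made by the authors with RMA, per the submitters' processing notes, which name RMA and limma without versions or settings. The probe annotation, the genome build and any filters are not given in the sources used here. The authors' deposited table also holds a log2 fold change and a p-value for each gene with a symbol, per the file headers. Whether that p-value is adjusted is not stated. It differed by at most 8.13e-05 from the unadjusted p of a limma fit on all rows made here. In the authors' deposited table Tspan7 has a log2 fold change of 5.08 and Bgn of -4.23.

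The full table held 35556 rows. A run of 6612 rows with the lowest probe set numbers carried no gene symbol and was taken as the control range and left out, a boundary set from the numbering after the files had been opened. The remaining 28944 probe sets were tested with no filter on level. A gene symbol was given in the authors' table for 20193 of them, each symbol once, so no choice among probe sets of a gene arose. Of these symbols 19457 matched a RefSeq gene of the GRCm38.p6 assembly, which served for chromosome and gene order, and 736 did not. For empty vector replicate 2, 91 values were stored with 3 digits, and 81 of them belonged to genes with a symbol. Those 81 were the genes with a deposited p of 1e-05 to 9e-05.

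The groups were compared with limma (lmFit and eBayes, default settings, version 3.58.1 in R 4.3.3), as the Myolinc line minus empty vector, two-sided, with Benjamini-Hochberg adjustment over the 28944 probe sets or over the 20193 genes and a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 2.18. Standard errors are the moderated ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With 2 arrays against 2 an exact permutation test of a single value cannot go below 0.333, so only the model across all probe sets was used. The labels call the arrays biological replicates but do not name separate transfections or selections, and the p-values measure only the spread between these arrays, which may be technical.

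The 23 gene lists, with 807 entries of which 752 were measured, were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists. They covered study genes, the Filip1 neighbourhood, myogenic regulators, sarcomere and contractile genes, fusion and adhesion, inhibitors of differentiation, cell cycle, p53 targets, matrix, TGF-beta, YAP and SRF targets, interferon response, cytokines and NF-kB targets, cholesterol biosynthesis, ATF4 and unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, and markers of adipocytes, osteoblasts and chondrocytes, endothelium, macrophages and leukocytes, neurons and glia, and epithelium. With the preset correlation 7 lists passed, with an estimated correlation 0 did, and with fry 7 did. These were not the same 7: with fry the sarcomere list (adjusted p = 0.0604) did not pass and the ATF4 and unfolded protein response list (0.0119) did. Fry also asks a different question. It tests whether the genes of a list changed at all, whereas camera compares a list with the other genes, so the counts of 7 are not like for like. With an estimated correlation camera tests on the 2 residual degrees of freedom, which leaves it little power over 23 lists. Tardbp, a study gene, was not analysed here.

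Named genes were the 15 largest rises and 15 largest falls past the threshold whose groups did not overlap, leaving out 10 predicted or unnamed genes changed at least 2-fold. To these were added up to 4 members of each list with the smallest p, the study genes, the Filip1 neighbourhood and the members of any count of 5 or fewer. A few genes that this rule takes are not reported here. Further list members named as examples were chosen after their values were seen: Lats2, Egr1, Ttn, Chrng, Loxl1, Cth, Id3, Tmem8c, Pfkp, Hk1 and others that were the exceptions of a list. The lists, the test, the rule and a first set of other settings were fixed before the data were examined.

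That first set held a replicate block, a trended and robust variance model, leaving out the lower-level probe sets, a further quantile normalization, centring on array medians, the rows of the workbook alone, leaving out each array, other thresholds and an ordinary linear model. Added after the data were seen were a fit with the control range, recovery of the values stored with 3 digits, removal of chromosome medians, and the authors' p adjusted. Data were simulated with 200 changed probe sets of 28944 and independent normal noise of the moderated spread of these arrays. There the fit recovered 15.2% of changes of 0.5 on the log2 scale, 92.8% of changes of 1 and 99.4% of changes of 2. Of its calls 8.73% were false, above the nominal share. In the real data 1934 probe sets passed, far more than were changed in the simulation, so these shares do not carry over directly.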

Results

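C2C12 cells are a mouse myoblast line that can be driven to form contractile myotubes. Here they were kept in growth medium and carried either an empty expression plasmid or the same plasmid with Myolinc, a long noncoding RNA. Cells with plasmid were selected with Zeocin, and the Myolinc cells were kept as a polyclonal line. Total RNA was hybridised to 4 Affymetrix arrays, 2 for each group. The median log2 value of an array lay between 7.24 and 7.35 over the 28944 probe sets tested, of which 20193 named a gene. The number of arrays limits the precision of every value. The files held no probe set under the name of Myolinc, so the level of the transfected RNA was not analysed here.

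The comparison asked which transcripts differed between the Myolinc line and the empty vector cells. Tspan7, which encodes a tetraspanin of the cell surface, rose most among named genes, from 6.66 ± 0.07 to 11.74 ± 0.07 on the log2 scale (SD, n = 2 per group), 33.8-fold higher in the Myolinc line. Bgn, which encodes the matrix proteoglycan biglycan, fell most, from 11.58 ± 0.01 to 7.34 ± 0.06, 18.8-fold lower in the Myolinc line. Of 20193 genes, 931 (4.61%) rose and 939 (4.65%) fell at an adjusted p under 0.05 in limma. Counts within the gene lists and families below are to be read beside these shares. Of the genes that rose 136, and of those that fell 93, changed at least 2-fold. The median size of the change among all 1870 genes past the threshold was 0.54 on the log2 scale.

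The genes with the largest rises included Nxf3 (log2 fold change 4.59, SE 0.11) and Nxf7 (2.35, SE 0.12), of the nuclear RNA export factor family. Magea5, a member of the MAGE family, rose by 4.26 (SE 0.08), and the sialyltransferase gene St6galnac5 rose by 3.80 (SE 0.09). The palmitoyltransferase gene Zdhhc15 rose by 3.37 (SE 0.09). Nefl, the light neurofilament subunit, rose by 3.27 (SE 0.06). The muscle genes Smyd1, needed for assembly of myosin into sarcomeres, and Xirp2, an actin-binding protein of striated muscle, rose by 3.10 (SE 0.06) and 2.84 (SE 0.18). The amino acid transporter gene Slc6a15 rose by 2.71 and Gfra1, a receptor for glial cell line-derived neurotrophic factor, by 2.31. Cd34, a surface marker of quiescent satellite cells and of other progenitors, rose by 2.24 (SE 0.10). Gpnmb, Klhl13 and Art3 completed the 15 largest rises, with log2 fold changes of 2.43, 2.40 and 2.21.

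Among the genes with the largest falls, Gpr149 fell by 3.98 (SE 0.07) and the water channel gene Aqp5 fell by 3.17 (SE 0.07). Of the late cornified envelope genes, Lce1g (-3.05, SE 0.28) and Lce1h (-2.71, SE 0.08) fell. F3, the tissue factor that starts blood clotting, fell by 2.79 (SE 0.08), and Edn1, which encodes the vasoconstrictor endothelin-1, fell by 2.69 (SE 0.20). Grem1, a secreted antagonist of bone morphogenetic proteins, fell by 2.58 (SE 0.09). The monocyte chemokine genes Ccl7 (-2.43, SE 0.09) and Ccl2 (-2.42, SE 0.08) fell. Stmn2 (-2.65), Fam198b (-2.55), the keratin gene Krt14 (-2.41), the potassium channel subunit gene Kcnmb1 (-2.34) and Ccnb1ip1 (-2.30) fell as well. The adjusted p of these 30 genes lay between 0.001601 and 0.0173. Of the 15 largest rises 11, Tspan7 among them, started in empty vector cells below the median level over probe sets, 7.27, and 5 of the 15 largest falls ended below it in the Myolinc line, so the sizes of these changes depend on low readings.

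**Figure D1:**
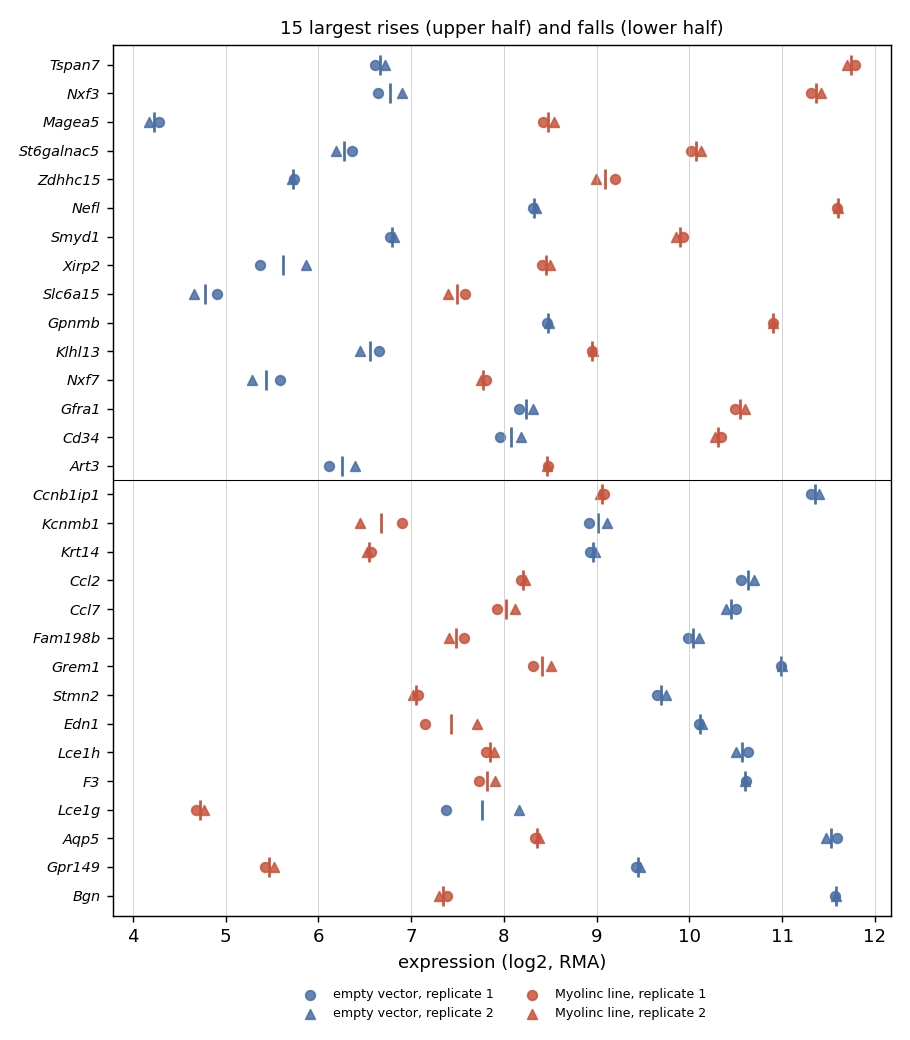
Expression (log2, RMA) of the 15 named genes with the largest rises and the 15 with the largest falls, with each array as a point, replicate 1 as a circle and replicate 2 as a triangle, empty vector in blue and the Myolinc line in red, and group means as vertical bars. The groups do not overlap for any of the 30 genes, and the differences run from 5.08 for Tspan7 to -4.23 for Bgn.

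Calls rest on limma's moderated test with Benjamini-Hochberg adjustment. The arrays of the groups did not overlap for any of the 1870 genes, which chance alone gives for a share of 0.333 of genes. Without empty vector replicate 1, and likewise without empty vector replicate 2, 0 genes passed in limma, with 3639 and 3322 at an unadjusted p under 0.05; without Myolinc replicate 1 the count was 644, and without Myolinc replicate 2 it was 1226. With the control range of probe sets kept in the fit it was 887, with a replicate block 362, with a trended and robust variance model 4342 and with the lower-level probe sets left out 4346. An ordinary linear model gave 0, with 4577 at an unadjusted p under 0.05. Each group holds a single selected line as far as the labels say, so line and plasmid could not be separated.

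The genes that the study is concerned with were looked at next, because the series title names muscle differentiation. Of the 7 measured study genes, Acta1, the skeletal muscle actin, fell from 10.28 ± 0.11 to 9.55 ± 0.10 (log2 fold change -0.73, SE 0.09, adjusted p = 0.0258), and the other 6 did not pass. Acta1 did not pass with a replicate block (adjusted p = 0.0647), without empty vector replicate 1 (0.198) or 2 (0.192), or without Myolinc replicate 1 (0.0550), while it did in the other limma fits, from 0.000403 to 0.0487, and its log2 fold change lay between -0.81 and -0.61 throughout. Myod1, the myogenic transcription factor, stood at 11.51 ± 0.05 in empty vector cells and 11.57 ± 0.03 in the Myolinc line (adjusted p = 0.590). Myogenin (Myog) and embryonic myosin heavy chain (Myh3), which come on during differentiation, had log2 fold changes of 0.06 (SE 0.09) and -0.05 (SE 0.06). The proliferation marker Mki67 had -0.16 (SE 0.09) and the cell cycle inhibitor Cdkn1a -0.07 (SE 0.06). Filip1 stood at 5.85 ± 0.27 and 5.96 ± 0.05 (log2 fold change 0.10, SE 0.14, adjusted p = 0.747). Myog, Myh3 and Filip1 lay below the median level over probe sets in both groups, so their values say little about a change at low expression. Adjusted over the list alone, Acta1 was again the gene that passed, and the list as a set did not pass (camera, adjusted p = 0.460).

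Of the 7 genes of the Filip1 neighbourhood, taken in the gene order of the GRCm38.p6 assembly, Col12a1, a collagen gene, fell by 0.72 (SE 0.07, adjusted p = 0.0177) and 6 did not pass. Cox7a2 had a log2 fold change of 0.27 (SE 0.06), Tmem30a 0.23 (SE 0.06), Senp6 -0.16 (SE 0.06), Myo6 0.25 (SE 0.12) and Impg1 0.01 (SE 0.07). Adjusted over the list alone, 2 rose and 1 fell. The set did not pass (camera, adjusted p = 0.920), and its median of 0.10 and mean of 0.00 (-0.00306) differed in sign.

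Targets of TGF-beta, YAP and SRF passed downward as a set with the preset correlation. Of 32 measured genes 16 fell, 1 rose and 15 did not pass, and adjusted over the list alone 21 fell and 2 rose. The contractile genes Tagln (-1.50, SE 0.06) and Myl9 (-1.09, SE 0.06), the inhibitory SMAD gene Smad7 (-0.69, SE 0.06) and the Hippo pathway kinase gene Lats2 (-0.86, SE 0.11) fell. Egr1, an immediate early gene, rose by 0.58 (SE 0.06). The median log2 fold change of the list was -0.38 (camera, adjusted p = 2.14e-09), with adjusted p = 0.280 with an estimated correlation. Here and below, that last setting rests on 2 residual degrees of freedom, so not passing in it says little.

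Sarcomere and contractile genes passed upward as a set with the preset correlation, though most members did not pass singly. Of 70 measured genes 47 had a positive log2 fold change, 15 rose, 3 fell and 52 did not pass, and adjusted over the list alone 20 rose and 6 fell. Actn3, the fast-fibre alpha-actinin, rose by 1.67 (SE 0.06), Ttn, the giant protein titin, by 1.40 (SE 0.18) and Smyd1 as above. The acetylcholine receptor subunit genes Chrnd (1.67, SE 0.09) and Chrng (1.17, SE 0.09) and the receptor kinase gene Musk (1.35, SE 0.06) rose, while the other receptor subunits of the list did not pass. The genes that fell were the actin genes Acta1 and Actc1 (-0.54, SE 0.06) and the Z-disc gene Ldb3 (-0.34, SE 0.06). The median of the list was 0.09 and its mean 0.28 (camera, adjusted p = 0.00248), with adjusted p = 0.868 with an estimated correlation and 0.0604 with fry.

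Genes of oxidative phosphorylation passed upward as a set with the preset correlation, though few members passed singly. Of 52 measured genes 2 rose, the ATP synthase subunit gene Atp5o (0.48, SE 0.06) and the complex III gene Uqcrq (0.36, SE 0.06), 0 fell and 50 did not pass, while 44 had a positive log2 fold change. Adjusted over the list alone, 10 rose and 1 fell. The median was 0.16 (camera, adjusted p = 2.13e-05), with adjusted p = 0.280 with an estimated correlation.

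Cholesterol biosynthesis genes passed downward as a set with the preset correlation. Of 25 measured genes 10 fell, 1 rose and 14 did not pass, and adjusted over the list alone 16 fell and 2 rose. Among those that fell were the lanosterol demethylase gene Cyp51 (-1.06, SE 0.08), the isomerase gene Idi1 (-0.93, SE 0.07) and Sc4mol (-0.72, SE 0.07). The median was -0.26 (camera, adjusted p = 3.79e-05), with adjusted p = 0.280 with an estimated correlation.

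Of 31 p53 target and DNA damage genes, 8 fell, 2 rose and 21 did not pass, and adjusted over the list alone 12 fell and 3 rose. Gadd45g (-0.87, SE 0.06), the death receptor gene Tnfrsf10b (-0.57, SE 0.06), Mdm2, the ubiquitin ligase of p53 (-0.52, SE 0.06), and the nuclease gene Aen (-0.46, SE 0.06) fell, whereas Gadd45a (0.62, SE 0.10) and Ccng2 (0.63, SE 0.08) rose. The set passed downward (camera, adjusted p = 0.00154), with adjusted p = 0.461 with an estimated correlation. Of 35 hypoxia and glycolysis genes, 8 fell, 2 rose and 25 did not pass, and adjusted over the list alone 13 fell and 3 rose. The mitophagy receptor gene Bnip3 (-1.09, SE 0.08), the pyruvate dehydrogenase kinase gene Pdk1 (-1.05, SE 0.08) and the prolyl hydroxylase gene P4ha2 (-0.69, SE 0.07) fell, whereas the glycolytic enzyme genes Pfkp (0.59, SE 0.08) and Hk1 (0.40, SE 0.07) rose. This set also passed downward (camera, adjusted p = 0.00254), with adjusted p = 0.369 with an estimated correlation.

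Of 39 cytokine, chemokine and NF-kB target genes, 8 fell, 2 rose and 29 did not pass, and adjusted over the list alone 10 fell and 3 rose. Besides Ccl2 and Ccl7, the prostaglandin synthase gene Ptgs2 (-1.82, SE 0.08) and the chemokine gene Cxcl5 (-1.76, SE 0.08) fell, while Tnfaip2 (0.41, SE 0.07) and the cytokine gene Il34 (0.46, SE 0.06) rose. The set passed narrowly (camera, adjusted p = 0.0454), with adjusted p = 0.461 with an estimated correlation. It did not pass with a replicate block (adjusted p = 0.0842), without empty vector replicate 1 (adjusted p = 0.0892), without Myolinc replicate 1 (0.145), with the lower-level probe sets left out (0.109) or after a further quantile normalization (0.0550).

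**Figure D2:**
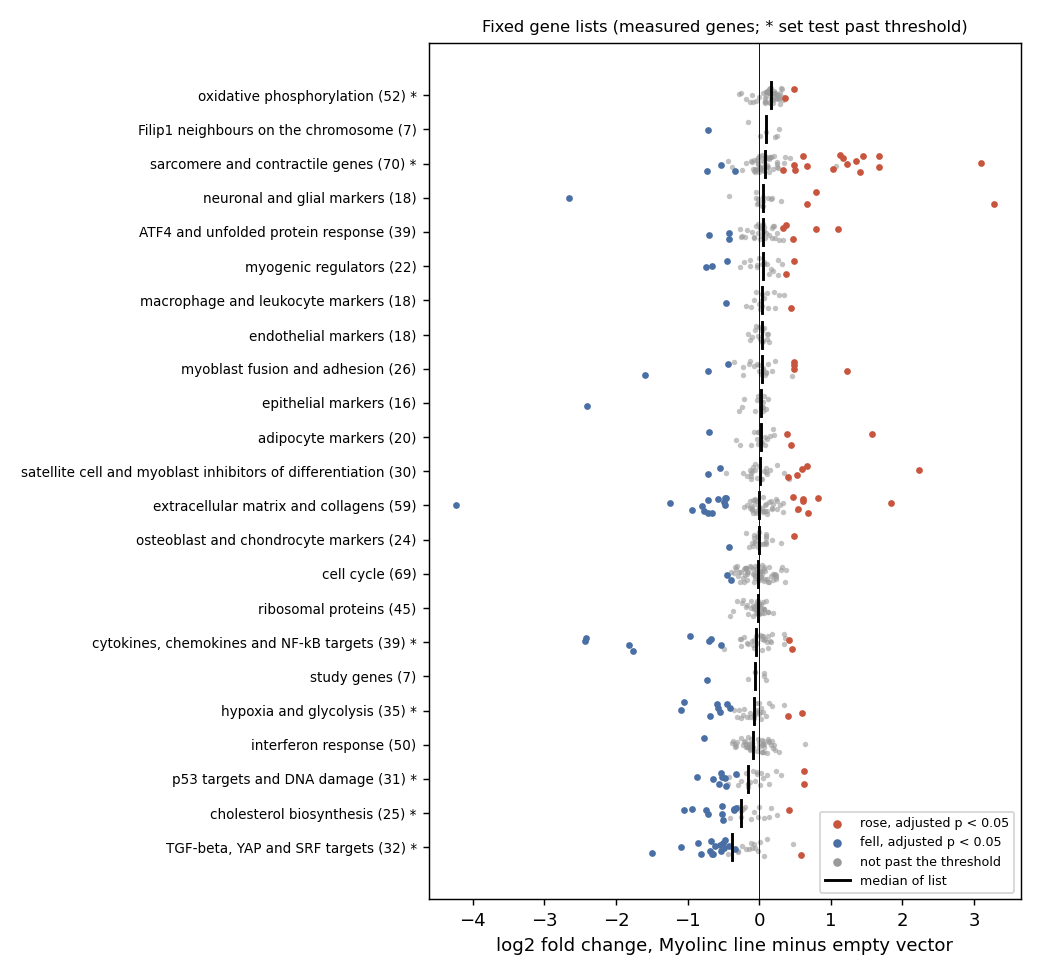
Log2 fold change (Myolinc line minus empty vector) of each measured member of the 23 gene lists, red where it rose, blue where it fell and grey where it did not pass, with the median of each list as a black bar, the measured number in parentheses and an asterisk on the 7 lists that passed the set test with the preset correlation. The lowest median is -0.38 (TGF-beta, YAP and SRF targets, 32 genes) and the highest 0.16 (oxidative phosphorylation, 52 genes).

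The other gene lists did not pass as sets with the preset correlation. Of 22 myogenic regulators 2 rose, among them Myf5 (0.38, SE 0.07), and 3 fell, Srf (-0.74, SE 0.06), Rbm38 (-0.66, SE 0.07) and Tead4 (-0.45, SE 0.08), with 2 and 4 adjusted over the list alone (set adjusted p = 0.940). Of 26 fusion and adhesion genes 4 rose and 3 fell, with 4 and 5 adjusted over the list alone (set adjusted p = 0.940). In that list the laminin receptor gene Itga7 rose by 1.23 (SE 0.06) and the myomaker gene, listed as Tmem8c, by 0.48 (SE 0.08), while the metalloprotease gene Adam12 fell by 1.59 (SE 0.08). The adhesion genes Cdh15 and Jam2 (both 0.49) also rose, and Boc (-0.72) and Dock5 (-0.44) fell. Of 30 satellite cell genes and inhibitors of differentiation 5 rose and 2 fell, with 7 and 3 adjusted over the list alone (set adjusted p = 0.658). The Notch pathway genes Notch3 (0.67, SE 0.06) and Hey1 (0.60, SE 0.06) rose, and Id1 (-0.72, SE 0.06) and Id3 (-0.54, SE 0.08), which encode inhibitors of MyoD-type factors, fell. Bhlhe41 (0.52), Snai2 (0.40) and Cd34 were the other genes that rose. Of 69 cell cycle genes, Mybl2 (-0.45, SE 0.06) and Mcm10 (-0.40, SE 0.06) fell and 67 did not pass, with 0 adjusted over the list alone (set adjusted p = 0.320, or 0.0370 without Myolinc replicate 2, where the set passed downward).

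Of 59 matrix genes 7 rose and 13 fell, with 11 and 14 adjusted over the list alone (set adjusted p = 0.595). Besides Bgn, the type I collagen gene Col1a1 (-1.25, SE 0.06) and Timp3 (-0.93, SE 0.06) fell, while Postn (1.84, SE 0.09) and Loxl1 (0.82, SE 0.06) rose. Of 50 interferon response genes Irgm1 fell (-0.77, SE 0.07), also when adjusted over the list alone (set adjusted p = 0.242). Of 39 genes of the ATF4 and unfolded protein responses 5 rose and 3 fell, with 7 and 4 adjusted over the list alone (set adjusted p = 0.456). With fry this set passed upward (adjusted p = 0.0119). Cth (1.09, SE 0.16) and Aldh1l2 (0.80, SE 0.08), of amino acid and folate metabolism, rose, and the endoplasmic reticulum genes Herpud1 (-0.71, SE 0.06) and Dnajb9 (-0.42, SE 0.06) fell. Ddit4 (0.47), Shmt2 (0.38) and Slc7a5 (0.32) also rose, and Dnajc3 (-0.42) fell. None of 45 ribosomal protein genes passed over all genes, a count of 0 that also held when adjusted over the list alone (set adjusted p = 0.239).

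Markers of other cell types moved singly rather than as sets. Of 20 adipocyte markers 3 rose, Lpl (1.57, SE 0.12), Scd1 (0.44) and Lipe (0.39), and Fasn fell (-0.70, SE 0.06), with 3 and 3 adjusted over the list alone (set adjusted p = 0.575). Of 18 neuronal and glial markers Nefl, Mtap2 (0.79, SE 0.06) and Gap43 (0.66, SE 0.07) rose and Stmn2 fell, with 4 and 2 adjusted over the list alone (set adjusted p = 0.348). Of 24 osteoblast and chondrocyte markers Spp1 (0.49, SE 0.06) rose and Col10a1 (-0.43, SE 0.06) fell, with 1 and 1 adjusted over the list alone (set adjusted p = 0.940). Of 18 macrophage and leukocyte markers Cd14 (0.44, SE 0.08) rose and Cd68 (-0.46, SE 0.06) fell, with 1 and 1 adjusted over the list alone (set adjusted p = 0.558). Of 16 epithelial markers Krt14 fell, also when adjusted over the list alone (set adjusted p = 0.456), and of 18 endothelial markers 0 passed either way (set adjusted p = 0.940). The macrophage and leukocyte, epithelial and endothelial lists each had fewer than 5 members at or above the median level over probe sets, 7.27. Their set results therefore rest mostly on low readings. Median and mean differed in sign for the epithelial (0.03 and -0.17), osteoblast and chondrocyte (-0.01 and 0.01) and myogenic regulator lists (0.05 and -0.01).

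Changed genes were unevenly spread over the chromosomes, a property examined only after the gene counts were known. On chromosome 8, which carries Acta1, 20 genes rose and 101 fell, and on chromosome 2 45 rose and 137 fell, whereas on chromosome 10 89 rose and 19 fell and on chromosome 16 66 rose and 14 fell. The median log2 fold change of expressed genes was -0.13 on chromosome 8 and -0.14 on chromosome 2, and 0.08 on chromosome 10 and 0.16 on chromosome 16. With the chromosome medians removed, Acta1 had a log2 fold change of -0.61. Of the genes taken by the naming rule, 5 that had passed then no longer did. The 2 that changed sign, Myh3 and Impg1, had not passed, and 112 kept sign and call. The cell cycle genes that fell, Mybl2 and Mcm10, lie on chromosome 2, so the shift of that chromosome is part of their falls.

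**Figure D3:**
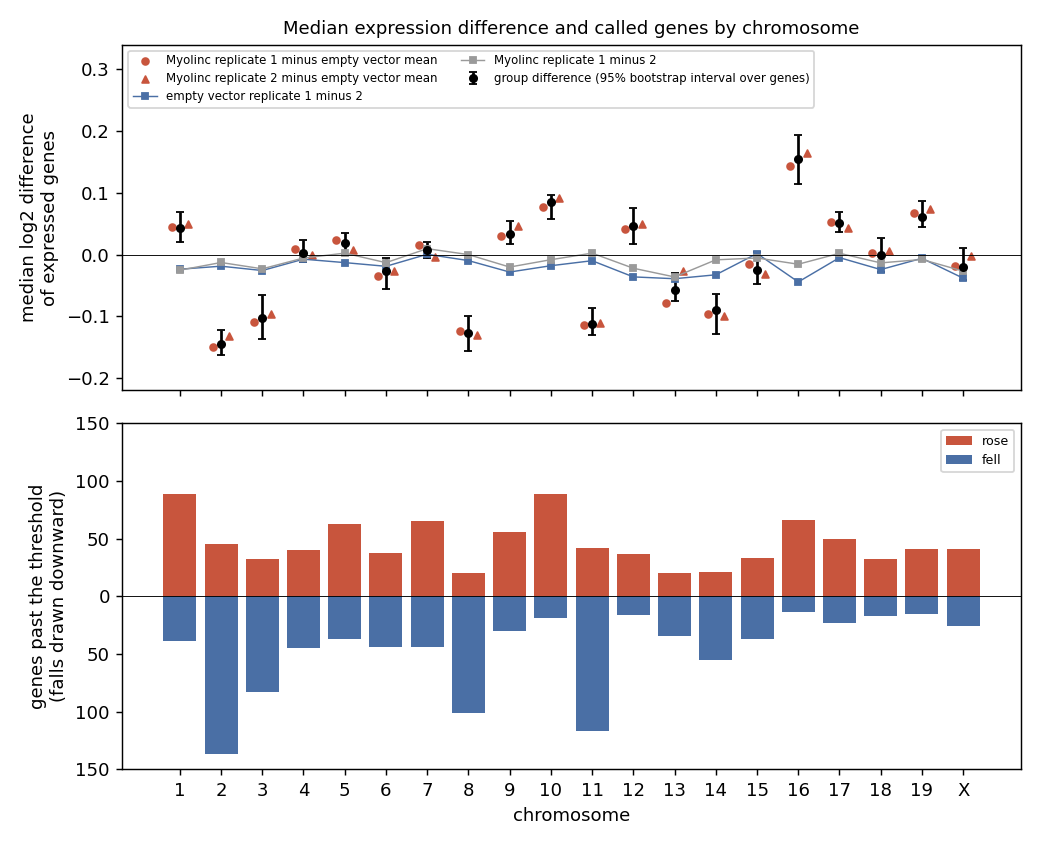
Median log2 difference of expressed genes by chromosome (top) for the group difference with its 95% bootstrap interval over genes, for each Myolinc array against the empty vector mean and for replicate 1 minus replicate 2 within each group, and the number of genes that rose or fell (bottom). The group medians run from -0.14 on chromosome 2 to 0.16 on chromosome 16, with an SD of 0.08 over chromosomes, against 0.01 for the differences within either group.

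The arrays of the Myolinc line were less alike than those of the empty vector cells, mainly in probe sets without a gene symbol. The SD of the log2 difference over probe sets was 0.36 between the Myolinc replicates and 0.15 between the empty vector replicates, and over genes it was 0.19 (0.185) and 0.14 (0.145). On the first principal component, with 58.1% of the variance, Myolinc replicate 1 lay at 42.0, Myolinc replicate 2 at 0.34 and the empty vector arrays at -18.2 and -24.1. On the second, with 35.0% of the variance, Myolinc replicate 2 lay at -34.6 and the other arrays between 8.9 and 14.1.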

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

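The fit that holds the control range was chosen after the values were seen. Outside the probe sets compared in the report, 7 of the 6612 probe sets of the control range passed the threshold between the groups in a fit on all rows, 2 higher and 5 lower in the Myolinc line. They drew attention because these probe sets name no gene and were not part of any comparison. The largest of the 7 differences was 1.33 on the log2 scale in size, and the median residual SD of the control range was 0.22, against 0.08 for the probe sets compared. What these probe sets measure was not analysed here.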

How the results depend on the processing

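The fit with the control range, the recovered 3-digit values, the removed chromosome medians and the authors' p adjusted were chosen after the data were seen. The signs of the 1870 called genes are not read as a measure of stability, since the groups did not overlap for them and most settings left their log2 fold changes as they were. From 1870 genes and 1934 probe sets the number past the threshold went to 362 and 159 with a replicate block, where 361 genes were shared. The labels name no common batch for arrays of the same replicate number, and there are 2 pairs. The differences between replicates correlated between the groups with r = 0.215 across probe sets, so a shared effect of replicate number stays open. The number past the threshold went to 4342 and 5363 with a trended and robust variance model, and to 4346 and 5262 with the lower-level probe sets left out. It went to 887 and 331 with the control range in the fit, whose wider spread enters the shared variance and whose rows raise the number of probe sets adjusted over to 35556, and to 887 genes with the authors' p adjusted. At an adjusted p under 0.01 it was 127 and 100, and with a fold of at least 2 as well 229 and 277. An ordinary linear model, with 2 residual degrees of freedom, gave 0 and 0, with 4577 and 5842 at an unadjusted p under 0.05. Leaving out an array, with the spread of the lone array taken from the other group, gave 0 to 1226 genes and 0 to 2271 probe sets. Both counts of 0 came from leaving out an empty vector array, with a smallest adjusted p of 0.151 and 0.147. The balance of 931 genes that rose and 939 that fell moved to 675 and 938 on centring on array medians, to 894 and 684 with chromosome medians removed, and to 210 and 152 with a replicate block. With an estimated correlation 0 of the 7 lists passed in camera, with 3 at an unadjusted p under 0.05, while 6 or 7 passed in the other settings with all 4 arrays. The estimated correlation setting tests on 2 residual degrees of freedom, which leaves little power whatever the correlation. The 3 lists were TGF-beta, YAP and SRF (estimate 0.0102), cholesterol biosynthesis (-0.00109) and oxidative phosphorylation (-0.00182), against the preset 0.01. For these 3 a higher correlation does not account for the loss. Among the 7, the sarcomere (0.184) and p53 (0.0508) lists had higher estimates. Lists and genes that did not pass changed sign as follows, by median or log2 fold change. After centring these were fusion (-0.00544), inhibitors of differentiation (-0.0343), adipocyte (-0.0160), endothelial (-0.00540), macrophage (-0.00167), epithelial (-0.0141) and Impg1 (-0.0332). With chromosome medians removed they were study genes (0.0200), matrix (0.00167), osteoblast (0.0215), Myh3 (0.0626) and Impg1 (-0.0267). With lower-level probe sets left out they were interferon (0.0594) and osteoblast (0.0835). The study gene, endothelial, macrophage and epithelial lists were not tested in that setting, with fewer than 5 members left in each. After quantile normalization they were cell cycle (0.00258), endothelial (-0.0181), macrophage (-0.0225), epithelial (-0.0252) and Impg1 (-0.0590). With arrays left out the ranges were -0.0471 to 0.207 for the Filip1 neighbourhood, -0.0236 to 0.0319 for inhibitors, -0.0402 to 0.0312 for matrix, -0.0518 to 0.00205 for ribosomal proteins, -0.0512 to 0.0408 for osteoblast, -0.0674 to 0.0853 for endothelial, -0.00426 to 0.105 for macrophage, -0.0711 to 0.10 for epithelial, -0.0888 to 0.291 for Filip1, -0.0189 to 0.148 for Myog and -0.0471 to 0.0640 for Impg1. Except where the construction is named, the cause was not tested. The mean over probe sets of a gene was not run, since the authors' table gives each symbol for a single probe set. Whether any of the 8751 probe sets without a symbol belong to the same genes was not analysed here. An adjusted p of the authors' own was not used either, since their table was read as unadjusted.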

Other observations

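The gene families of the next paragraphs were chosen after the results were seen, as were the tests of chance spread over chromosomes, of blocks within chromosomes, of chance concentration on the X, of the whole X, of expressed X neighbours, of genomic DNA, in general and in replicate 1 alone, and of background. The families came from reading through 282 changed genes and 19 name families, so their counts carry no test of enrichment. Of 18 late cornified envelope genes, which are clustered genes of skin barrier proteins, 6 fell and 0 rose, from Lce1g (-3.05, SE 0.28) and Lce1h (-2.71, SE 0.08) to Lce1f (-0.43, SE 0.07). Of the genes that fell, Lce1f (5.37 in empty vector cells and 4.95 in the Myolinc line) and Lce1c (6.56 and 5.64) lay below the median level over probe sets in both groups. Of 18 MAGE genes 4 rose and 0 fell: Magea5 (4.26, SE 0.08), Magea6 (2.09, SE 0.06), Magea3 (1.91, SE 0.19) and Magef1 (0.58, SE 0.08). Magea6 (4.44 in empty vector cells and 6.53 in the Myolinc line) and Magea3 (4.84 and 6.75) stayed below the median level over probe sets, 7.27. The sizes of their changes depend on low readings.

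Of 44 imprinted genes measured, which are expressed from a single parental copy, 9 rose and 0 fell, while the median of the list was 0.04. The largest rises were those of Zim1 (1.95, SE 0.14), the growth regulator Plagl1 (1.34, SE 0.06), Igf2r (1.04, SE 0.08) and Peg3 (1.02, SE 0.08), and H19 rose by 0.73 (SE 0.06). Of 27 genes of oxidative and metal stress 6 fell and 2 rose. The metallothionein genes Mt2 (-1.63, SE 0.09) and Mt1 (-1.29, SE 0.07), the quinone reductase gene Nqo1 (-1.47, SE 0.07) and the heme oxygenase gene Hmox1 (-1.02, SE 0.06) fell, and Gsta4 (0.64, SE 0.06) rose.

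Chromosome medians differed between the lines, with an SD of 0.0777. Of 10000 shuffles of genes over chromosomes none gave an SD as large (permutation p = 1e-04, the smallest these can give), which argues against chance placement. After a trend on expression level was removed 0.995 of the SD was kept, which argues against a level effect. The larger within-group SD was 0.177 of that between groups, which argues against an array property that varies between replicates. A processing effect shared by both arrays of a group would cancel there, and the labels name no batch, so it stays open. A copy-number difference between the selected lines is a candidate explanation that these values do not decide. Medians of adjacent blocks of 25 genes correlated with r = 0.676, against 0.28 and 0.306 for the replicate differences, so some correlation is seen without any group difference. Blocks of a chromosome share its median, so r = 0.676 largely restates the unequal medians, whatever their cause. With the chromosome medians removed r was 0.296 (permutation p = 0.000999, the smallest these 1000 shuffles can give), against 0.169 and 0.234 for the replicate differences. On chromosome 8 the shift was uneven, with block medians of -0.05 to 0.01 in the first 4 blocks and of -0.42 to -0.31 in blocks 11 to 15, whereas all block medians were positive on chromosome 10 (0.0043 to 0.28) and on chromosome 16 (0.06 to 0.26). DNA copy number was not analysed here, and an effect of Myolinc on these genes stays open.

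Of 760 X-linked genes 15 (1.97%) rose at least 2-fold, against 121 of 18680 others (0.648%), and 7 of the X-linked genes fell at least 2-fold (Fisher's exact test, two-sided p = 0.000284 for rises and 0.0939 for falls). At any fold 41 rose and 26 fell, a balance that did not pass against the other chromosomes (Fisher's exact test, p adjusted over chromosomes 0.0772). The X was singled out because of these rises, so blocks of 25 neighbouring genes were shuffled over the genome. In a share of 0.0252 of 10000 shuffles some chromosome held rises or falls of 2-fold as unevenly. This argues only weakly against chance, since the shuffles allow for the choice of chromosome and direction but not for that of the 2-fold cut. A gain of the whole X was not seen, since expressed X genes had a median of -0.02 (-0.0199). A gain of the segments around these genes was not seen in their pooled neighbours, from which all 15 genes were left out. The nearest 3 tested genes on each side had a median of 0.05 (0.0516), and the nearest 3 expressed genes -0.01 (-0.0104), against 2.15 for the 15 genes. A gain that held only genes among the 15, or that lay at few of them, could be missed this way. The test on expressed neighbours was added after the first had been read, and both gave the same answer. Activation of single X genes, through Myolinc or through the history of the line, may underlie the pattern, as a hypothesis that was not tested.

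Between the Myolinc replicates 419 probe sets differed over 2-fold, 411 of them higher in replicate 1 and 380 without a gene symbol, against 1 between the empty vector replicates. Of the 419, 0 passed the group comparison, which their selection nearly fixed, since the replicate difference is part of the spread used by that test. The 419 held 283 distinct sets of values, since 172 probe sets shared all 4 values with another. The small nucleolar RNA probe set Snord115 read 8.28 and 3.35 in the Myolinc replicates and 5.56 and 5.18 in the empty vector arrays. Transcription of the Snord115 host region stays open: the neighbouring single-copy genes had a median difference of -0.09 (-0.0888), but 5 of the 7 looked for were measured, without the host genes Snrpn and Snurf, and 2 of the 5 were expressed. A background higher for all dim probe sets alike is argued against by an excess of receptor genes over level-matched genes whose bootstrap interval over genes starts at 0.154. Genes were matched on level alone, so a background that differs between gene families stays open. Genomic DNA in the RNA of replicate 1 is a candidate explanation, since 1239 olfactory, vomeronasal and taste receptor genes were higher there by 0.174 more than matched genes, against 0.00658 between the empty vector replicates. Against the empty vector mean this excess was 0.134 in replicate 1 and -0.05 (-0.0488) in replicate 2. Genomic DNA in replicate 1 alone is argued against as the whole cause: chosen without use of replicate 2, the probe sets without a symbol that were over 2-fold above the empty vector mean in replicate 1 held 210 distinct sets of values, with a median of -0.32 (-0.321) in replicate 2, and 155 of the 210 lay below that mean. What lowered them in replicate 2 stays open, and no biological explanation was tested. The bounds for the genomic DNA tests were set after the differences had been seen.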
